A study of Mus musculus with 6 samples.

How the data were processed

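The series measured total RNA from the livers of 6 mice, 3 given the vector with GFP and 3 given the vector with the active form of CREB-H. All mice carried a knockout of Creb3l3 and were 8 weeks old, per the labels. RNA was converted to single-stranded cDNA, fragmented and labelled with biotin, per the labels' protocols, so that each array held 1 sample in 1 colour. The deposited values are log2 signals, 1 per probe set and array, made by the authors with the Transcriptome Analysis Console, per the submitters' processing notes. The version, the summarisation of probes, the normalization between arrays and any filter are not given in the sources used here. The log2 scale was inferred from the values, which ran from 1.42 to 13.9 with near-equal quartiles on all arrays, and genes had not been centred. Scanner files were not used here, so neither background nor detection calls could be examined and no floor was set; differences of dim probe sets may be understated. Scan dates and batches were not analysed here.

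All 41345 probe sets of the table were tested. Gene names came from GEO's platform annotation, and the reference table of assembly GRCm38.p6 held the Entrez ID of 23328 of the 23521 probe sets with 1 gene symbol, with no symbol changed. A further 1814 probe sets had several genes and 16010 were not listed, and neither kind was named. Where a gene had more than 1 probe set, which was so for 1082 of 22180 genes, the one with the highest mean over all 6 arrays was used. No coordinates are given because the table names no genome build.

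The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, group as the single term) on the deposited log2 values without further normalization. Tests were two-sided with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. An SE is that of the moderated log2 fold change, and 95% intervals use its degrees of freedom. A single gene compared outside the model had an exact permutation test over the 6 arrays, which cannot go below 0.1.

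The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 33 lists held 594 genes, of which 529 were measured, and were drawn up from general knowledge of liver biology, CREB-H and cell types of the liver. Some genes belong to more than 1 list. Each list was tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 33 lists, and again with an estimated correlation and with fry. Named genes were Creb3l3, 10 fixed genes, and up to 4 members of each list with the lowest unadjusted p. The 10 largest rises and the 10 largest falls that passed without overlap between the groups were also named. Where fewer passed, places were filled by the lowest unadjusted p among non-overlapping genes with a log2 fold change of at least 1 in size. Predicted genes, receptor gene families of smell and pheromones, and immunoglobulin or T cell receptor segments were left out of that part of the rule. With 3 against 3 arrays, chance alone gives non-overlapping groups in 10% of genes.

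The alternatives tried were quantile normalization, centring each array on its median, leaving out the dimmest 25% or 50% of probe sets, limma-trend with and without robust fitting, array weights, the replicate number as a block, each array left out in turn, 1 probe set per gene, the mean of a gene's probe sets in the list tests, and thresholds with a fold of at least 1.5 or 2. Alternatives chosen after the data were seen were a term for Y-linked signal (mean of Kdm5d, Eif2s3y and Uty above 5) and the 4 arrays without such signal. No scaling moved the median log2 fold change of all probe sets by more than 0.1, from -0.015 to 0.005 under quantile normalization and to 0.003 after centring. No pair of arrays held the same values.

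The model was tested on simulated data with the levels and spread of the real probe sets and 3 arrays per group. Of 50 probe sets changed by each size, 10% were recovered at a log2 change of 0.5, 56% at 1, 92% at 2 and 96% at 4, with 8 false calls among 41125 unchanged probe sets. The simulated noise was independent between genes, unlike that of real arrays. The changed probe sets were drawn from the brighter ones, and all sizes were changed in the same simulated data. With fewer changed probe sets the adjustment is stricter, so these shares may overstate recovery in the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.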

Results

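Gene expression was measured in the liver of 6 mice that lack CREB-H (gene symbol Creb3l3), a transcription factor anchored in the endoplasmic reticulum membrane that is cleaved to release its active part. An adeno-associated virus directed to the liver supplied either the active form of CREB-H, named CREB-H-ΔTC in the labels, or green fluorescent protein (GFP) as the control. Each group held 3 mice, listed as biological replicates, and livers were taken 2 weeks after the injection. Total RNA from each liver was hybridised to 1 array, and 41345 probe sets were measured on a log2 scale. Signals ran from 1.42 to 13.9, and the medians of the arrays lay between 4.98 and 5.01. The number of arrays limits the precision. The median standard error (SE) of a log2 fold change was 0.142. Replicate 3 of each group carried signal from the Y-linked genes Kdm5d, Eif2s3y and Uty, with a mean of 7.83 in the GFP array and 7.67 in the CREB-H array, against 3.15 to 3.39 in the other 4 arrays. Xist, the RNA that silences 1 X chromosome in females, was low on the same arrays (4.43 and 3.75, against 10.8 to 11.3). The labels do not give the sex of the animals. A fit that leaves out replicate 3 of either group keeps Y-linked signal in 1 group only. Such a fit therefore also holds the difference of that array.

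The comparison of CREB-H with GFP asks which liver genes respond when the active factor is put back into mice without it. The supplied gene was examined first, because it checks the labels. Creb3l3 (probe set 17243183, Entrez 208677) had a signal of 6.30 ± 0.32 (SD, n = 3) with GFP and 7.19 ± 0.43 (SD, n = 3) with CREB-H. The log2 difference was 0.89 with an SE of 0.25. The GFP arrays read 6.55, 5.93 and 6.40 and the CREB-H arrays 6.73, 7.25 and 7.58, so that the groups did not overlap, in the direction of the labels. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow, and the limma adjusted p of 0.647 did not pass. Which part of the transcript the probes read is not given in the sources used here, so signal from the knockout allele and from the vector could not be separated.

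Apoa4, an apolipoprotein of triglyceride-rich lipoproteins, was strongly raised by CREB-H. Its signal (probe set 17516908, Entrez 11808) rose from 9.72 ± 0.22 to 13.42 ± 0.27 (SD, n = 3 per group), a 13.0-fold increase with a 95% confidence interval of 9.73 to 17.4. Asic5 (probe set 17398441, Entrez 58170), a member of the acid-sensing ion channel family, fell from 10.26 ± 0.15 to 8.40 ± 0.05 (SD, n = 3 per group). Its fall was 3.64-fold, with a 95% interval of 0.228 to 0.332 for the ratio of CREB-H to GFP. In both genes all 3 CREB-H arrays lay beyond all 3 GFP arrays. These were the only 2 of the 41345 probe sets that passed the limma test after Benjamini-Hochberg adjustment, with adjusted p = 0.00786 for Apoa4 (log2 fold change 3.70, SE 0.18) and 0.0202 for Asic5 (-1.86, SE 0.11). At an unadjusted p below 0.05 there were 2850 probe sets, 1210 higher and 1640 lower with CREB-H, against 2067.2 that chance would give if no probe set changed. A split of the arrays that mixed the groups, GFP replicates 1 and 2 with CREB-H replicate 2 against the others, gave 2866. Both arrays with Y-linked signal lay on the same side of that split, so its number does not measure chance alone. Splits that mixed the groups with these arrays on opposite sides, as in the real comparison, gave 1294 to 1781, below the 2067.2 of chance. Such a split places any effect of CREB-H within its groups, where it adds to the spread and can lower the count. These numbers therefore do not measure chance alone either. The excess of lower probe sets was not kept: there were 1397 higher and 1403 lower under quantile normalization, and 1400 higher and 1387 lower after median centring.

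**Figure D1:**
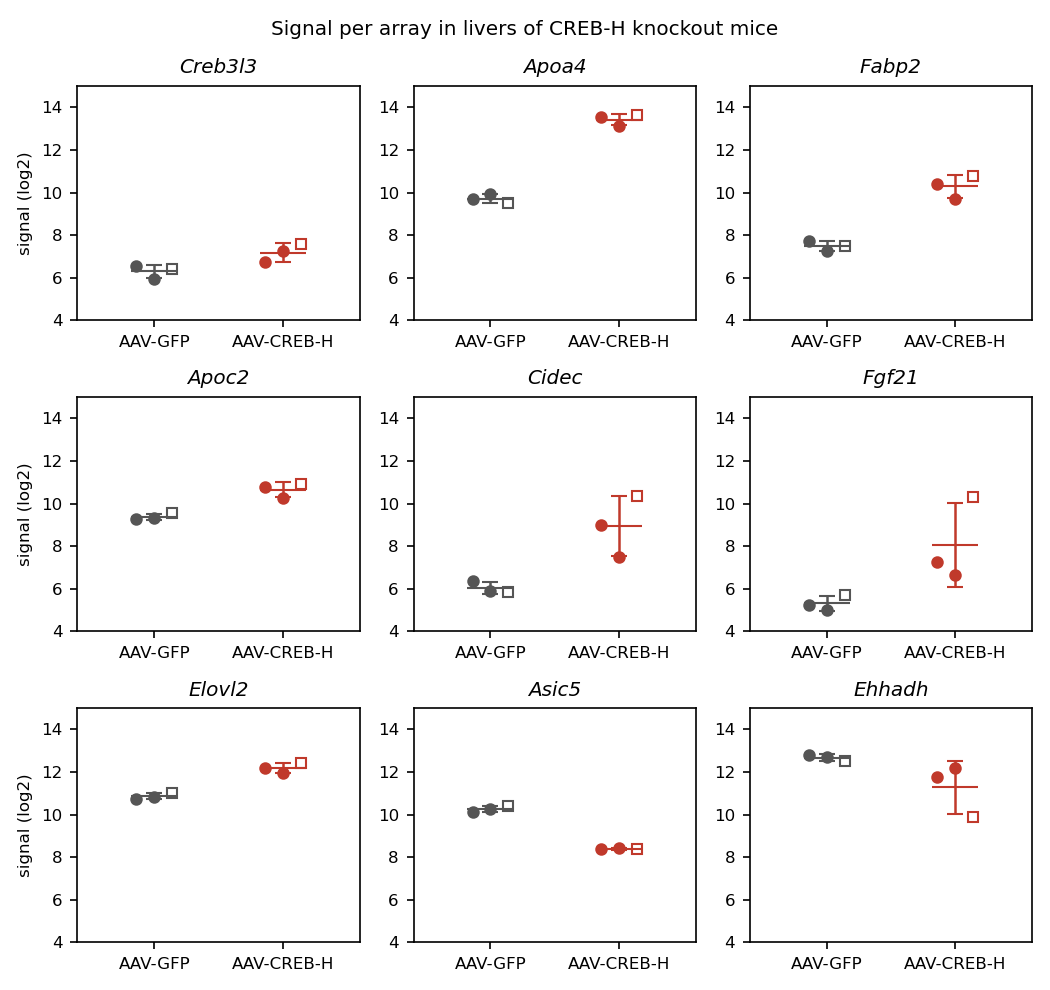
Signal (log2) of 9 genes on each array for the GFP and the CREB-H group, with horizontal lines for the group means and error bars for the SD (n = 3 per group); open squares mark replicate 3 of each group, the arrays with Y-linked signal. Apoa4 separates the groups by 3.70 and Asic5 by -1.86, while the SD of the CREB-H group is 1.96 in Fgf21 and 1.42 in Cidec.

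The log2 fold change of Apoa4 lay between 3.50 and 3.86 and that of Asic5 between -1.94 and -1.77 under all alternatives. Leaving out any single array other than CREB-H replicate 2 ended the call of Apoa4 (log2 fold change 3.60 to 3.81, adjusted p = 0.0552 to 0.136), and leaving out any of the 6 ended that of Asic5 (-1.94 to -1.78, adjusted p = 0.0876 to 0.305). With a term for Y-linked signal, added after the data were seen, Asic5 no longer passed (log2 fold change -1.86, SE 0.11, adjusted p = 0.0693) while Apoa4 did (SE 0.19, adjusted p = 0.0498); the fit had 5.95 degrees of freedom in place of 6.83. On the 4 arrays without Y-linked signal, neither passed (3.50 and -1.77, adjusted p = 0.516 each), and with the replicate number as a block neither passed (adjusted p = 0.243 each). Over all alternatives the adjusted p ran from 0.00458 to 0.516 for Apoa4 and from 0.0116 to 0.516 for Asic5.

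Among genes that did not pass, those named here had the lowest unadjusted p among genes that differed by at least 1 on the log2 scale without overlap between the groups. The naming rule left out predicted genes and those with symbols ending in Rik, such as C730002L08Rik, which is given below. Fabp2, the intestinal fatty acid-binding protein, had a log2 difference of 2.79 (SE 0.28, adjusted p = 0.21). Elovl2, which elongates polyunsaturated fatty acids, differed by 1.32 (SE 0.16, adjusted p = 0.347). Gas6, the ligand of the TAM receptor kinases, differed by 1.91 (SE 0.25), and Nanp, a phosphatase of sialic acid synthesis, by 1.57 (SE 0.22). A further probe set of Nanp had 0.97 (SE 0.23). Apoc2, the activator of lipoprotein lipase, differed by 1.28 (SE 0.19), and the phospholipid scramblase Plscr1 by 1.00 (SE 0.16). Map2k6, a kinase upstream of p38, had 1.05 (SE 0.18), Tram2 1.24 (SE 0.21) and Tnfaip8l1 1.78 (SE 0.31). In the other direction, 5 further genes met the same rule. The small nucleolar RNAs AF357425 and AF357355 had log2 differences of -1.19 (SE 0.15) and -1.84 (SE 0.33). Slc17a8, a vesicular glutamate transporter, had -1.14 (SE 0.22). Ehhadh, an enzyme of peroxisomal fatty acid oxidation, had -1.40 (SE 0.56), and Cyp4a31, of the fatty acid hydroxylase family Cyp4a, had -1.14 (SE 0.62). In both of these the CREB-H array with Y-linked signal was far below its group, at 9.88 against 11.75 and 12.21 in Ehhadh and at 7.96 against 10.29 and 10.36 in Cyp4a31. Without that array the differences were -0.70 and -0.35. With 1 array left out, 83 of the 143 genes taken by the naming rule moved by over 1.5 times in at least 1 fit; Apoa4, Asic5 and Creb3l3 did not.

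The list of reported CREB-H targets stood higher with CREB-H as a group (camera adjusted p = 0.00219, median log2 fold change 0.30; adjusted p = 0.503 with an estimated correlation). Of its 16 measured members 10 were higher and 6 lower. Only Apoa4 passed over all probe sets, and 3 members passed when adjusted over the list alone: Apoa4, Apoc2 and Cidec. Cidec, which promotes the growth of lipid droplets, went from 6.03 ± 0.29 to 8.94 ± 1.42 (SD, n = 3 per group), a log2 difference of 2.91 (SE 0.65). The hormone gene Fgf21 went from 5.31 ± 0.36 to 8.07 ± 1.96, a log2 difference of 2.76 (SE 0.89), which did not pass either adjustment. Its CREB-H arrays read 7.27, 6.63 and 10.30, and the difference was 1.64 without the last. Among the other genes of the fixed set, differences were 0.46 (SE 0.17) for Apoa5, 0.495 (SE 0.17) for the gluconeogenic enzyme gene Pck1 and 0.41 (SE 0.15) for Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation. The secreted proteins Crp, Apcs and Hamp differed by -0.07 (SE 0.14), 0.34 (SE 0.53) and -0.12 (SE 0.38). None of these 6 passed, and the last 3 turned sign: Crp was 0.01 and Hamp 0.06 without GFP replicate 2, Hamp was 0.28 without CREB-H replicate 3, and Apcs was -0.26 without CREB-H replicate 2. Pck1 was 0.31 without GFP replicate 3. Lipoprotein and lipase regulation was higher as a group (camera adjusted p = 0.0101, median 0.09; adjusted p = 0.619 with an estimated correlation), with 19 of 26 members higher. In that list 1 member passed over all probe sets, and Apoa4, Apoc2 and the lipoprotein receptor gene Scarb1 (0.45, SE 0.10) passed when adjusted over the list alone. The mean of the lipoprotein list, which includes Apoa4 at 3.70 and Apoc2 at 1.28, was 0.28. Both genes also belong to the targets list, so the results of the 2 lists are not independent. The targets list was lost without GFP replicate 3 (median 0.19, adjusted p = 0.0634), a fit that keeps Y-linked signal in the CREB-H group only. With the preset correlation, it passed camera with a term for that signal (adjusted p = 0.0125) and among the 4 arrays without it (0.0295). The median of the targets list was 0.18 without CREB-H replicate 2. The lipoprotein list was lost without GFP replicate 1 (median 0.03, adjusted p = 0.0853). Its median was 0.16 among the 4 arrays without Y-linked signal and -0.04 between the 2 arrays with it. Over all alternatives the adjusted p ran from 0.000304 to 0.503 for the targets and from 0.000704 to 0.619 for the lipoprotein list.

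Fatty acid oxidation and ketogenesis was the 1 list that stood lower with CREB-H after adjustment (camera adjusted p = 0.000711, median log2 fold change -0.28; adjusted p = 0.69 with an estimated correlation). Of its 31 measured members 25 were lower and 6 higher, and none passed over all probe sets or when adjusted over the list alone. The members with the lowest unadjusted p went both ways. Cpt2, which works in the mitochondrial carnitine shuttle, differed by -0.40 (SE 0.11). The ketone body enzyme Bdh1 differed by 0.99 (SE 0.25), the receptor Ppara, which activates fatty acid oxidation genes, by 0.63 (SE 0.19), and Cpt1a, given above, was also higher. The median was -0.70 between the 2 arrays with Y-linked signal, -0.13 among the other 4 arrays and -0.15 without CREB-H replicate 3 (adjusted p = 0.00524 and 0.00961; 4.54e-06 to 0.709 over all alternatives).

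Fatty acid and triglyceride synthesis stood higher (camera adjusted p = 0.0398, median 0.20; adjusted p = 0.69 with an estimated correlation), with 13 of 20 members higher. None passed over all probe sets, and 1, the polyunsaturated fatty acid elongase Elovl5 (0.91, SE 0.17), passed when adjusted over the list alone. The desaturases Fads1 and Fads2 differed by 0.71 (SE 0.21) and 1.17 (SE 0.38), and the nuclear receptor Pparg by 0.93 (SE 0.33). Fads2 was 0.74 without GFP replicate 3. This list was lost under quantile normalization (adjusted p = 0.103) and median centring (0.0693). It was also lost under both filters on dim probe sets (0.0708 and 0.132), with the mean of a gene's probe sets (0.0513), and without GFP replicate 1 (0.0704), GFP replicate 3 (0.0868) or CREB-H replicate 1 (0.0585). Without CREB-H replicate 2 its median was 0.01 (adjusted p = 0.657), without CREB-H replicate 1 it was 0.31, and without CREB-H replicate 3 it was 0.37 (adjusted p = 0.00177). Over all alternatives the adjusted p ran from 0.00177 to 0.709.

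Other lipid lists did not pass. Lipid droplet and triglyceride storage had a median of -0.12 and a mean of 0.00 (8 of 21 higher, camera direction down, adjusted p = 0.285), and the positive mean included the 2.91 of Cidec. Its member Plin2, a droplet coat protein, differed by -0.72 (SE 0.28), Mogat1 by -0.29 (SE 0.11) and Hsd17b11 by -0.54 (SE 0.27). Without CREB-H replicate 3, Plin2 differed by -0.42 and Hsd17b11 by -0.22, and the list median was 0.01 without GFP replicate 1. Cholesterol synthesis had a median of 0.16 (16 of 20 higher, adjusted p = 0.0747), with Lss at 0.37 (SE 0.18; 0.24 without CREB-H replicate 2) and Fdft1 at 0.61 (SE 0.33). Fdft1 was 0.32 without GFP replicate 2 and 0.97 without GFP replicate 3. That list passed with array weights (adjusted p = 0.0402), among the 4 arrays without Y-linked signal (0.00123), and without GFP replicate 3 (0.00177), CREB-H replicate 1 (0.00434) or CREB-H replicate 3 (0.0273). Its median was 0.31 without GFP replicate 3, 0.06 without GFP replicate 2 (adjusted p = 0.685) and 0.03 without CREB-H replicate 2 (0.986). Bile acid synthesis and transport had a median of -0.03 (11 of 23 higher, adjusted p = 0.624), although its camera direction was up. Abcg5, which with Abcg8 forms the sterol exporter of the hepatocyte, passed when adjusted over that list alone (0.57, SE 0.10), and Abcg8 differed by 0.45 (SE 0.13).

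**Figure D2:**
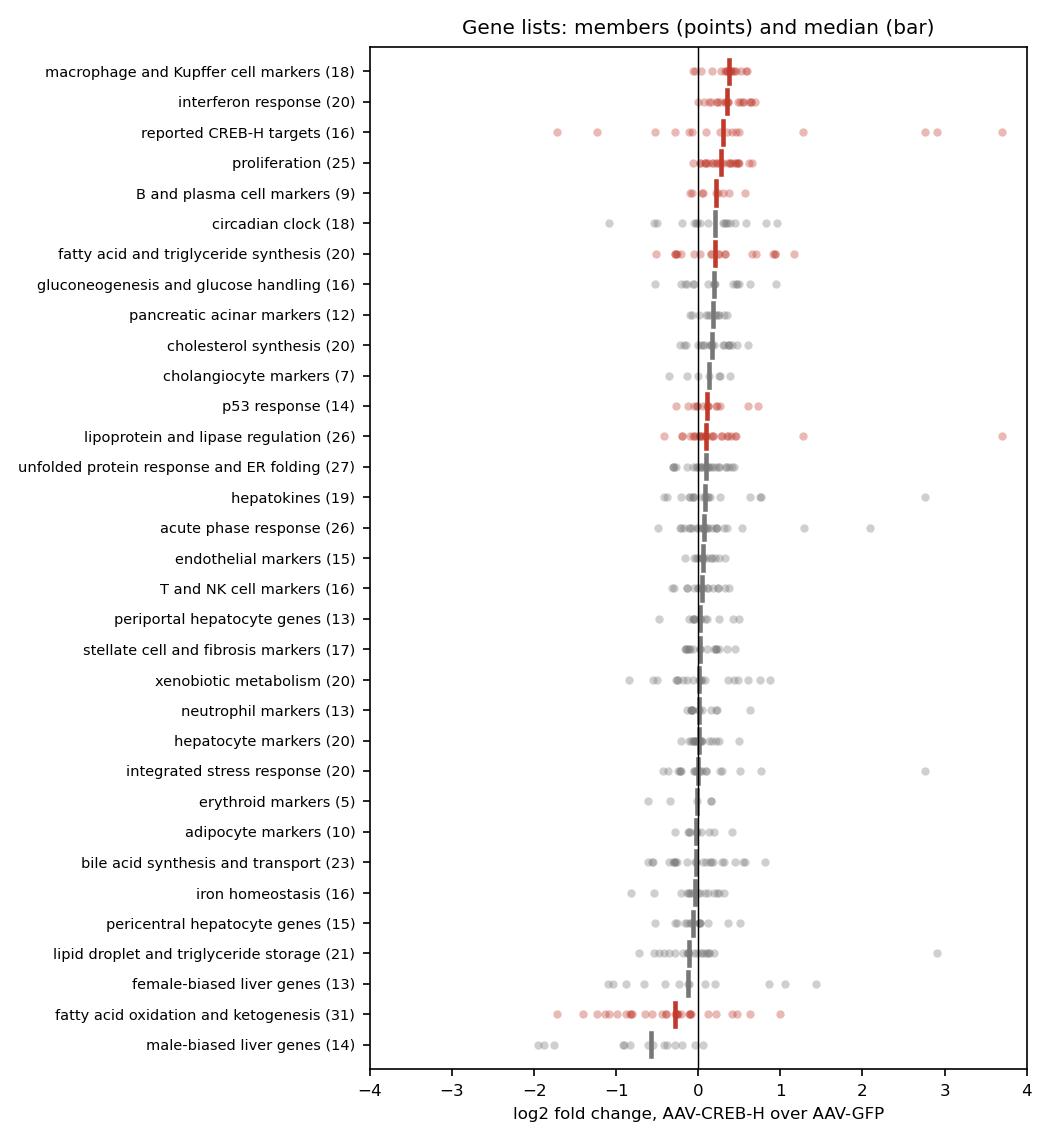
Log2 fold change of CREB-H over GFP (horizontal axis) for the measured members of the 33 gene lists, with points for genes, bars for list medians and the number of measured members in brackets; red marks lists past the camera test with a preset correlation. Of the red lists, fatty acid oxidation and ketogenesis has a negative median (-0.28) and the others have positive medians, the highest being macrophage and Kupffer cell markers at 0.37.

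Lists of other liver functions did not pass as groups, and no member passed over all probe sets. The medians of lists that did not pass depended on single arrays: with 1 array left out, all 24 moved by over 1.5 times in at least 1 fit, and 20 turned sign. Medians of the lists that passed also moved by over 1.5 times, except that of interferon response, but none turned sign. Gluconeogenesis and glucose handling had a median of 0.19 (10 of 16 higher, adjusted p = 0.135). Gys2, the liver glycogen synthase, passed when adjusted over that list alone (0.95, SE 0.17), and the glucose transporter gene Slc2a2 differed by 0.47 (SE 0.14). The list passed without GFP replicate 1 (adjusted p = 0.0194) or 2 (0.0149), and its median was -0.12 without GFP replicate 3 (adjusted p = 0.84). Hepatokines had a median of 0.08 (11 of 19 higher, adjusted p = 0.285), and Igfbp2, which binds insulin-like growth factors, passed when adjusted over that list alone (0.77, SE 0.16). The acute phase response had a median of 0.07 (17 of 26 higher, adjusted p = 0.455), with Itih4 at 0.21 (SE 0.10) and Itih3 at -0.49 (SE 0.23; -0.25 without CREB-H replicate 3). It passed without GFP replicate 2 (adjusted p = 0.0354) or CREB-H replicate 3 (0.0249; up to 0.932 over all alternatives). The metallothionein gene Mt2 differed by 2.09 (SE 1.42); its signal was 7.13 in GFP replicate 3 and at least 12.5 on the other 5 arrays, and the difference was 0.24 without that array. The unfolded protein response and ER folding had a median of 0.09 (19 of 27 higher, adjusted p = 0.285), with P4hb at 0.34 (SE 0.11) and the chaperone cofactor Dnajb9 at -0.31 (SE 0.13). The integrated stress response had a median of -0.01 against a camera direction of up (10 of 20 higher, adjusted p = 0.817), with Ddit3 at -0.37 (SE 0.12) and Atf5 at 0.76 (SE 0.27; 0.43 without CREB-H replicate 3). Its median was 0.01 after median centring. Iron homeostasis had a median of -0.03 (8 of 16 higher, adjusted p = 0.987), with Hjv at -0.53 (SE 0.18). Xenobiotic metabolism had a median of 0.01 (11 of 20 higher, adjusted p = 0.987). Cyp1a1 (0.44, SE 0.10) and Nqo1 (0.61, SE 0.12) passed when adjusted over that list alone. The circadian clock list had a median of 0.21 (11 of 18 higher, adjusted p = 0.285), with Nr1d2 at 0.34 (SE 0.14) and Clock at -0.54 (SE 0.27). It mixes genes that peak with Dbp and genes that peak with Arntl, which moved in opposite directions, as given below. Its median and the directional test can therefore miss a change of the clock. Clock was -0.30 without CREB-H replicate 1 and -0.86 without CREB-H replicate 3. The median of the clock list was 0.04 without GFP replicate 3 and 0.10 without GFP replicate 2.

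The interferon response and proliferation lists stood highest in the group test, by small amounts per gene. Of 20 interferon response genes 19 were higher (median 0.35, camera adjusted p = 1.81e-07; adjusted p = 0.503 with an estimated correlation). Ifit1 differed by 0.51 (SE 0.12), and the sensors of viral RNA Ifih1, Dhx58 and Ddx58 by 0.36 (SE 0.11), 0.54 (SE 0.17) and 0.49 (SE 0.15). Of 25 proliferation genes 24 were higher (median 0.28, camera adjusted p = 1.81e-07; adjusted p = 0.619 with an estimated correlation). Mcm2 and Mcm5, parts of the replicative helicase, differed by 0.48 (SE 0.11) and 0.49 (SE 0.18), and the mitotic genes Cdc20 and Plk1 by 0.36 (SE 0.10) and 0.41 (SE 0.14). These genes were dim, with GFP means from 4.95 (Mcm5) to 5.61 (Mcm2) against array medians of 4.98 to 5.01. The median of the proliferation list was 0.18 without CREB-H replicate 1 (adjusted p = 0.0004; 4.86e-12 to 0.619 over all alternatives). No member of either list passed over all probe sets or when adjusted over the list alone. The p53 response was higher with a median of 0.11 (9 of 14 higher, camera adjusted p = 0.0272; adjusted p = 0.619 with an estimated correlation). Its member Ccng1 passed when adjusted over the list alone (0.61, SE 0.11), and Btg2 differed by 0.73 (SE 0.34; 0.38 without GFP replicate 3). The p53 list was lost without GFP replicate 3 (adjusted p = 0.249), without CREB-H replicate 2 (0.403), without the dimmer 50% of probe sets (0.0586) and among the 4 arrays without Y-linked signal (0.0943), within a range of 0.00889 to 0.619. Its median was 0.19 without GFP replicate 1 (adjusted p = 0.0113). Markers of macrophages (median 0.37) and of B cells (median 0.22) were higher in the same comparison.

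Macrophage and Kupffer cell markers were higher with CREB-H, with 16 of 18 members higher (median 0.37, camera adjusted p = 0.00225; adjusted p = 0.845 with an estimated correlation). Cd68 differed by 0.46 (SE 0.19), Vsig4 by 0.60 (SE 0.27), and the complement genes C1qb and C1qc by 0.44 (SE 0.28) and 0.39 (SE 0.24). Without GFP replicate 3, Vsig4, C1qb and C1qc were at 0.39, 0.24 and 0.23, and without GFP replicate 2, C1qb and C1qc were at 0.70 and 0.61. Without CREB-H replicate 2, C1qb and C1qc were at 0.26 and 0.25, and Cd68 was at 0.30 without GFP replicate 1. This call was lost without GFP replicate 3 (median 0.17, adjusted p = 0.323) and without CREB-H replicate 2 (0.19, adjusted p = 0.31), and the median was 0.60 without GFP replicate 2 and 0.59 without CREB-H replicate 3 (adjusted p over all alternatives 7.17e-08 to 0.845). On the arrays with Y-linked signal the median of these markers deviated from the other arrays of the group by -0.52 with GFP and -0.66 with CREB-H. Leaving out 1 of these arrays therefore unbalances the groups, apart from any effect of CREB-H. B and plasma cell markers were higher with 7 of 9 members higher (median 0.22, camera adjusted p = 0.0398; adjusted p = 0.69 with an estimated correlation), with Cd79a at 0.57 (SE 0.18) and Ms4a1 at 0.38 (SE 0.15). That call was lost under median centring (adjusted p = 0.0548), both filters on dim probe sets (0.066 and 0.134), with a term for Y-linked signal (0.0628), and without GFP replicate 1 (0.0736), GFP replicate 3 (0.0946), CREB-H replicate 1 (0.0704) or CREB-H replicate 2 (median 0.14, adjusted p = 0.491). It was also lost with the replicate number as a block (0.0867), and the range was 0.00177 to 0.69. No marker in these lists passed over all probe sets or when adjusted over its list alone.

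The other marker lists did not pass. Hepatocyte markers had a median of 0.00 (10 of 20 higher, adjusted p = 0.817), with the transcription factor gene Cebpa at 0.50 (SE 0.20; 0.33 without CREB-H replicate 1). Pericentral hepatocyte genes had a median of -0.07 (7 of 15 higher, adjusted p = 0.312) and periportal genes 0.03 (7 of 13 higher, adjusted p = 0.699). T and NK cell markers had a median of 0.05 (10 of 16 higher, adjusted p = 0.778). Neutrophil markers had 0.01 (7 of 13 higher, adjusted p = 0.601), and Retnlg passed when adjusted over that list alone (0.64, SE 0.13). Retnlg was dim, with means of 3.33 with GFP and 3.96 with CREB-H, below the lowest array median of 4.98. Its limma adjusted p over all probe sets was 0.613. Adjustment over a list alone does not allow for the number of lists. Erythroid markers had a median of -0.02 over 5 measured genes (2 higher, adjusted p = 0.52), which was 0.02 after quantile normalization. Endothelial markers had 0.05 (12 of 15 higher, adjusted p = 0.285), stellate cell and fibrosis markers 0.02 (10 of 17 higher, adjusted p = 0.606), and cholangiocyte markers 0.13 (4 of 7 higher, adjusted p = 0.604), with Sox9 at -0.36 (SE 0.11) and Krt19 at 0.38 (SE 0.12). Pancreatic acinar markers had 0.18 (10 of 12 higher, adjusted p = 0.202). Leaving out CREB-H replicate 3 made the endothelial (adjusted p = 0.0305), stellate (0.00158) and pancreatic (0.00965) lists pass. That fit keeps Y-linked signal in the GFP group only. On CREB-H replicate 3 these lists had median deviations of -0.17, -0.46 and -0.31 from the other CREB-H arrays. The endothelial list also passed without GFP replicate 2 (0.00279), the stellate list among the 4 arrays without Y-linked signal (0.0202) and the pancreatic list without CREB-H replicate 1 (0.0264). Their adjusted p ran up to 0.94, 0.997 and 0.848 over all alternatives. Adipocyte markers had a median of -0.02 and a mean of 0.01 (4 of 10 higher, adjusted p = 0.827), and the median was 0.01 after quantile normalization.

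Liver genes that differ between the sexes varied most between arrays. Male-biased genes had a median of -0.58 (13 of 14 lower, camera adjusted p = 0.0651), with Elovl3 at -1.88 (SE 1.31) and Hsd3b5 at -1.95 (SE 1.85). Elovl3 was -0.86 without GFP replicate 3, -1.12 without CREB-H replicate 1 and -3.22 without CREB-H replicate 3. The test passed with a term for Y-linked signal (adjusted p = 6.88e-07), under quantile normalization (0.0368) and under median centring (0.0329). It also passed with the replicate number as a block (1.3e-07), among the 4 arrays without Y-linked signal (0.0153), and without GFP replicate 1 (0.00566), GFP replicate 2 (0.000328) or CREB-H replicate 3 (0.000152). The median was 0.47 without GFP replicate 3 (adjusted p = 0.323), and the adjusted p ran up to 0.845. Female-biased genes had a median of -0.13 against a camera direction of up (5 of 13 higher, adjusted p = 0.987), with Cyp17a1 at 1.05 (SE 0.87) and Fmo2 at 0.86 (SE 0.90). Without GFP replicate 3, Cyp17a1 and Fmo2 differed by -0.06 and -0.19, and Hsd3b5 by 0.15. Without GFP replicate 2 they moved the other way, to 1.68 for Cyp17a1, 1.35 for Fmo2 and -3.39 for Hsd3b5. The median of the female-biased list was -1.03 without GFP replicate 3 (adjusted p = 0.021) and 1.11 without CREB-H replicate 3 (adjusted p = 0.00637). Leaving out either of these arrays leaves Y-linked signal in 1 group only, so these changes cannot be read as effects of CREB-H. No member of either list passed over all probe sets or when adjusted over its list alone.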

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

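The tests with a term for Y-linked signal and with only the arrays without it were chosen after the data were seen. The count of 2 probe sets, 1 higher and 1 lower, was the same under quantile normalization, median centring, both filters on dim probe sets, limma-trend with and without robust fitting, array weights and the added fold of 1.5, and in each refit the same 2 probe sets passed. With 1 probe set per gene there were 2 lower calls, the added one being the long non-coding RNA C730002L08Rik (-1.84, SE 0.14, adjusted p = 0.0169), named here after its values were seen. With a fold of at least 2 and an unadjusted p there were 177 probe sets, 89 higher and 88 lower. With each array left out in turn limma called 0 to 2 probe sets, 0 to 2 higher and 0 lower, and 2335 to 3155 had an unadjusted p below 0.05. Every such fit gave 0 except that without CREB-H replicate 2, which called Apoa4 and 1 unnamed probe set (17526633). With the Y-linked term 1 probe set passed, higher, and 0 lower (3542 unadjusted). With only the 4 arrays without that signal limma called 0 in total, 0 higher and 0 lower (3338 unadjusted), with fewer samples in the fit.

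With the replicate number as a block limma called 0 probe sets, 0 higher and 0 lower (smallest adjusted p = 0.243, 3224 unadjusted), with fewer residual degrees of freedom. The labels pair no samples by number. Deviations from the group means correlated across probe sets at 0.078, 0.13 and 0.33 between arrays of the same number, and GFP replicate 1 correlated best with CREB-H replicate 2 (0.16), not with its own number.

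Of 33 lists 9 passed camera with a preset correlation. With an estimated correlation 0 passed (smallest adjusted p = 0.503), and with fry 0. With each array left out in turn 5 to 16 passed, 5 without CREB-H replicate 2 and 16 without CREB-H replicate 3. The fit with 16 keeps Y-linked signal in the GFP group only. The female-biased list turned from up to down without GFP replicate 3 (median -1.03, adjusted p = 0.021) and its median was 1.11 without CREB-H replicate 3 (adjusted p = 0.00637). Each of these fits leaves Y-linked signal in 1 group only. On the arrays with that signal the list deviated from the others of its group by -3.34 (GFP) and -3.76 (CREB-H). The turn goes with that imbalance and cannot be read as an effect of CREB-H. Interferon response, proliferation, and fatty acid oxidation and ketogenesis passed under 17 of their 19 alternatives each, all with the preset correlation. The other 2 were fry and the estimated correlation, which was 0.081, 0.31 and 0.28 for these lists against the preset 0.01. Creb3l3 kept its direction and stayed past no threshold under all 16 alternatives (log2 fold change 0.69 to 1.12, adjusted p = 0.445 to 0.807). Of 142 other named genes 131 kept their direction in every refit. Signal over background was not analysed here.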

Other observations

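Of the tests in this part, those of Y-linked signal, of sex (for the arrays numbered 3 and for GFP replicate 3) and exchange of arrays, and of the time of day were chosen after the results were seen, as were the genes of the next sentences. The 2 pathway lists were written down after the differences of Nanp, Gne, Elovl2, Elovl5, Fads1 and Fads2 had been seen. The class I antigen-presentation gene H2-K1 went from 10.35 ± 0.09 to 11.03 ± 0.01 (SD, n = 3 per group), a log2 difference of 0.68 (SE 0.10, limma adjusted p = 0.503). Ube2l6, the conjugating enzyme for Isg15, differed by 0.70 (SE 0.12), and the interferon-inducible apolipoprotein L gene Apol9a by 0.91 (SE 0.17). None passed. In sialic acid metabolism, Gne, the first enzyme of synthesis, differed by 0.60 (SE 0.11) and the transferase gene St3gal3 by 0.78 (SE 0.15), beside Nanp. One hypothesis was that CREB-H raises sialic acid metabolism as a whole. The 12 other members tested had a median log2 fold change of -0.06 and a mean of -0.08, and their mean plus 2 SE (0.03) lay below the 0.60 of Gne. This argues against a rise of that size over these 12 genes. The SE was taken over genes, which are not independent. The two-sided p of limma's camera test for that list was 0.267. Another was that the fatty acid elongation cycle rises as a whole with Elovl2, Elovl5, Fads1 and Fads2. The 9 other genes tested, of which Acot7 and Acsl4 are not enzymes of the cycle itself, had a median of -0.12. Their mean plus 2 SE over genes (0.18) lay below the 0.71 of Fads1, which argues against a rise of that size over these genes. A smaller rise stays open. The two-sided p of limma's camera test for that list was 0.746.

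For the number of probe sets past the threshold, other splits of the arrays were counted. Of the 10 splits of the 6 arrays into 3 and 3, 2 gave at least as many probe sets as the real split, itself included; the real one gave 2 and the highest other gave 5. The split with 5 set GFP replicates 1 and 2 and CREB-H replicate 2 against the other arrays. At an unadjusted p below 0.05 that split gave 2866 probe sets, against 2850 for the real one. It put both arrays with Y-linked signal on the same side, so it does not measure chance alone. Among splits with these arrays on opposite sides, the real one gave 2 and every other gave 0. Those others had 1294 to 1781 at an unadjusted p below 0.05. They place any effect of CREB-H within their groups, which adds to the spread and can lower the counts, so they do not measure chance alone either. The splits are too few for a share under 0.05.

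The arrays numbered 3 stood apart in both groups: with Y-linked signal as a term, 57 probe sets passed the limma test for that term, 25 higher and 32 lower on these 2 arrays, among them Cyp2b13 (-8.07), Cyp3a16 (-7.46) and Cyp2d9 (4.46), named after their values were seen. An exchange of these arrays between the groups is argued against by Apoa4, 4.12 higher in CREB-H replicate 3 than in GFP replicate 3, and another tissue or cell type by the lists of non-hepatocyte markers. None of these lists was higher on those arrays in both groups: taking the smaller of the groups for each list, the highest median deviation was -0.0493 (neutrophil markers), and the lowest was -0.66 (macrophage and Kupffer cell markers). The male-biased list exceeded the female-biased list in its deviation by 6.04 in the GFP group and 5.95 in the CREB-H group, consistent with male animals as replicate 3 and female animals as the others. A different effect of CREB-H in the sexes stays open: no probe set passed the limma interaction test (smallest adjusted p = 0.223, 2852 at an unadjusted p below 0.05), with 1 array per group with Y-linked signal and 2 without.

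GFP replicate 3 alone had low signals of Mt1 (8.16), Mt2 (7.13), Mfsd2a (6.65) and Lpin1 (8.46), with log2 differences of -5.68 to -3.14 from the mean of the other 5 arrays. Their median difference between CREB-H replicate 3 and the other CREB-H arrays was -0.188, which decides nothing about sex, because they were chosen for being low on GFP replicate 3 alone. A list of 16 other genes of the glucocorticoid and fasting response was written down before its difference on that array was computed. Its median was -1.46 in GFP replicate 3 against the other arrays (Igfbp1 -2.75, Zbtb16 -2.12, Fkbp5 -1.87). That lay below all 10000 random sets, which were matched on mean level alone and not on how genes vary together. Genes that vary together can fall outside such sets on any array that stands apart. The rank therefore cannot tell a glucocorticoid or fasting state from another difference of that animal. The list member Pdk4 was also lower in GFP replicate 3 (-1.99), but its signal was lower still in CREB-H replicate 3 (7.09 against 8.68). Cyp4a14 was higher in GFP replicate 3 (0.52). Sex alone, which predicts the same difference of replicate 3 in both groups, is argued against by that list: the GFP difference minus the CREB-H difference had a median of -1.34 and a mean plus 2 SE over the genes, which are not independent, of -0.52. A different feeding or stress state of that animal may account for this; the labels say nothing of it, and a sex difference that depends on the vector stays open.

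Clock genes differed in opposite directions in the 2 sets of arrays. The median of genes that peak with Dbp minus that of genes that peak with Arntl was 1.55 for CREB-H over GFP among replicates 1 and 2, and -0.85 between the arrays numbered 3, so that the smaller size was 0.848. Arntl itself differed by -2.20 and 1.14, and Nr1d1 by 1.91 and -0.93. On single arrays, the median signal of the Dbp genes minus that of the Arntl genes was 0.29, -0.84 and 1.85 with GFP. With CREB-H it was 1.12, 1.18 and 0.53, in the order of the replicates. The comparison between the arrays numbered 3 rests on 1 array per group and cannot be told apart from differences between single animals. The time of day at sacrifice could give the opposite directions, but only 11 of the 14 genes followed in both comparisons: Nr1d2, Ciart and Usp2 did not. Time of day and an effect of CREB-H on the clock that differs between the animals cannot be told apart, because the labels give no time of sacrifice.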
